A study of Mus musculus and Homo sapiens with 40 samples.

How the data were processed

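The samples were grouped by the genotype, diet, antibody and cell type in their labels, and the group sizes are those given at the start of the results. The mice were male littermates, and the labels describe separate animals. The HepG2 samples of a genotype are not described as separate cultures, so p-values on them measure only the spread between these samples, which may be technical.

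RNA libraries were made with a stranded mRNA kit and ChIP libraries by ChIPmentation, in which a transposase adds adapters to immunoprecipitated chromatin, per the labels' protocols. Per the submitters' processing notes the tools were cutadapt 2.7, HISAT2 2.1.0, Subread with featureCounts 1.6.4, SAMtools 1.9, R 3.5.1 and DESeq2 1.22.1, and Bowtie2 2.3.5, Picard 2.21.4, MACS2, bedtools 2.29.0 and deepTools 3.3.1, with builds hg38 and mm10. These notes do not say which step used which tool. The mouse RNA values deposited by the authors are TPM per gene in separate tables for the 2 diets, each with 48544 genes, and the step that made the TPM is not given in the sources used here. TPM divide by gene length and by the library's total, so they keep no depth, and a few abundant genes lower the share of all others. For HepG2 RNA the authors deposited a comparison table with mean signal (normalised counts) per genotype, log2 fold changes and adjusted p-values, which was used as given. Peaks were called per sample against its own input with MACS 2.2.7.1, per the file headers, with narrow LDB1 peaks at q 0.05 and broad H3K27ac peaks at q 0.01 and a broad threshold of 0.001. The deposited peak lists give, per peak, the pileup signal, the fold enrichment as a ratio to the input and the −log10 p-value and q-value, all of them the authors' own values. They were used to describe, rank or filter peaks within a list.

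Tests had been planned for counts. Since the mouse tables held TPM, limma 3.58.1 (R 4.3.3, statmod 1.5.0, trend and robust settings) was used in their place on log2(TPM + 1) after scaling by an unweighted trimmed mean (30% of log ratios and 5% of mean levels trimmed from each end). A fold change on this scale understates the change of low genes. Genes were tested at 1 TPM or more in at least as many libraries as the smaller group holds, within each diet's table. The interaction is the difference between the knockout effects of the 2 diets in a single fit of all 14 mouse libraries, scaled and filtered together. It can therefore differ, in sign too, from the difference between the fold changes fitted within each diet. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Exact zeros in TPM can be failed estimates, so such genes are given as listed at 0. Library numbers on the high-fat diet are column order only, because the column names do not match single samples. Within groups the log2 values of libraries correlated at 0.973 to 0.984 across genes, and scaling factors ran from 0.798 to 1.37 on regular chow and from 0.820 to 1.14 on the high-fat diet. No columns of samples outside the series' list were found (0).

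In all, 42 gene lists with 948 members, 925 of them in the tables, were fixed beforehand and tested with camera at a preset correlation of 0.01 where at least 5 members were tested. Lists share genes: 15 of 26 periportal and 17 of 27 pericentral members stand in another list. The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule takes LDB1 and 8 transcription regulators always, up to 5 genes per direction by largest fold change among called genes with mean TPM of at least 5 and no overlap between groups, up to 4 genes with the smallest adjusted p from each list past the threshold, 5 per direction for the interaction, 6 per direction for overlaps, up to 4 of the highest genes of marker lists, the 5 strongest shared LDB1 regions, and changed H3K27ac regions within 50 kb of named genes. The text leaves out some genes the rule names, and some are not reported here. Ncoa4, Malat1 and Neat1 were chosen after their values were seen, as were genes listed at 0 that fall outside it.

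Simulated data with known changes were used to test the RNA step. For regular chow, 200 of 8636 genes were changed, 166 were called with 4 false calls, and 75% of changes of the smaller and 87% of the larger planted size were recovered. For the high-fat diet, 200 of 11151 were changed, 180 were called with 9 false calls, and 79% and 92% were recovered. With no change planted, 0 genes were called in both cases. Noise was drawn independently for each gene, and changes were planted only in genes with mean TPM of at least 5. Other splits of the real libraries gave up to 10 genes on regular chow and 9 on the high-fat diet. The simulation therefore does not give the rate of false calls in the real data.

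Peaks were compared with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and figures drawn with matplotlib 3.10.9. Peaks overlapping by at least 1 bp were counted as shared. H3K27ac peaks of all libraries of a species were merged, and a region was lost when all controls and no knockout had a peak in it, and gained in the opposite case. Tag numbers differ between libraries, and weak peaks can be missed in a shallower library, so a region counted as lost or gained can also be a peak near the calling threshold. Mouse genes were placed with a RefSeq table of GRCm38, the assembly of mm10, which placed 8184 of 8930 tested genes (91.7%). Its genes carry no strand, so windows of 50 kb were drawn around gene bodies, where windows around transcription start sites had been planned. Alternatives were other scalings, filters and pseudocounts, each library left out, a replicate block, a common spread, an estimated correlation, other windows, stricter peaks, other overlaps and equal list lengths. Motif searches, gene lists in HepG2 cells, the overlap of HepG2 with mouse genes and peaks near HepG2 genes were not run, because no human genome or annotation was used here.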

Results

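The series measured what follows when LDB1 is removed from liver cells. LDB1 is a LIM-domain-binding adaptor that holds transcription factor complexes together and helps to bring distant enhancers to promoters. HepG2 is a human hepatocellular carcinoma line, and LDB1 was disrupted in it with Cas9 and a guide to the first exon of the gene. In mice, Ldb1 was deleted from hepatocytes with Alb-Cre, a recombinase driven by the albumin promoter, in floxed male littermates on a C57BL/6 background. RNA was sequenced from 2 control and 2 knockout HepG2 samples, from 3 control and 3 knockout mice on regular chow at 7 weeks of age (12.5% of kcal as fat), and from 4 control and 4 knockout mice at 23 weeks after 15 weeks on a high-fat diet (60% of kcal as fat). Chromatin immunoprecipitation (ChIP) of LDB1 was done in 2 control HepG2 samples. ChIP of H3K27ac, a histone mark of active promoters and enhancers, was done in 2 control and 2 knockout HepG2 samples and in 3 control and 2 knockout mice of 7 weeks. The mouse RNA values were TPM, which keep no sequencing depth, so the depth of the RNA libraries is unknown. The regular chow libraries listed 8255 to 9728 genes at 1 TPM or more and the high-fat diet libraries 10600 to 11599. The LDB1 ChIP libraries held 13243967 and 12241094 tags after filtering, the HepG2 H3K27ac libraries 9904107 to 13521080 and the mouse H3K27ac libraries 9905051 to 12788883, per the peak file headers.

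Ldb1 RNA was low in the knockout hepatocytes on both diets. On regular chow Ldb1 was at 2.46, 1.25 and 1.48 TPM in the 3 controls and at 0.293, 0.378 and 0.0898 TPM in the 3 knockouts, and every knockout lay below every control. The fitted log2 fold change was -1.17 (SE 0.14), with a limma adjusted p of 0.0520, which did not pass the threshold. On the high-fat diet Ldb1 fell from 7.24 ± 0.219 to 2.38 ± 0.323 TPM (SD, n = 4 and 4), a log2 fold change of -1.37 (SE 0.10, limma adjusted p = 0.00205). The effect on Ldb1 did not differ detectably between the diets (interaction log2 0.15, limma adjusted p = 0.762). This does not show an equal loss. On regular chow the means, 1.73 TPM in controls and 0.254 TPM in knockouts, lay near the pseudocount of 1, which shrinks the fold change there more than on the high-fat diet. The TPM cover the whole transcript, parts outside the floxed segment included, so they are an upper limit of intact Ldb1 RNA. LDB1 could not be looked up in the HepG2 RNA data, where genes carried identifiers without symbols.

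**Figure D1:**
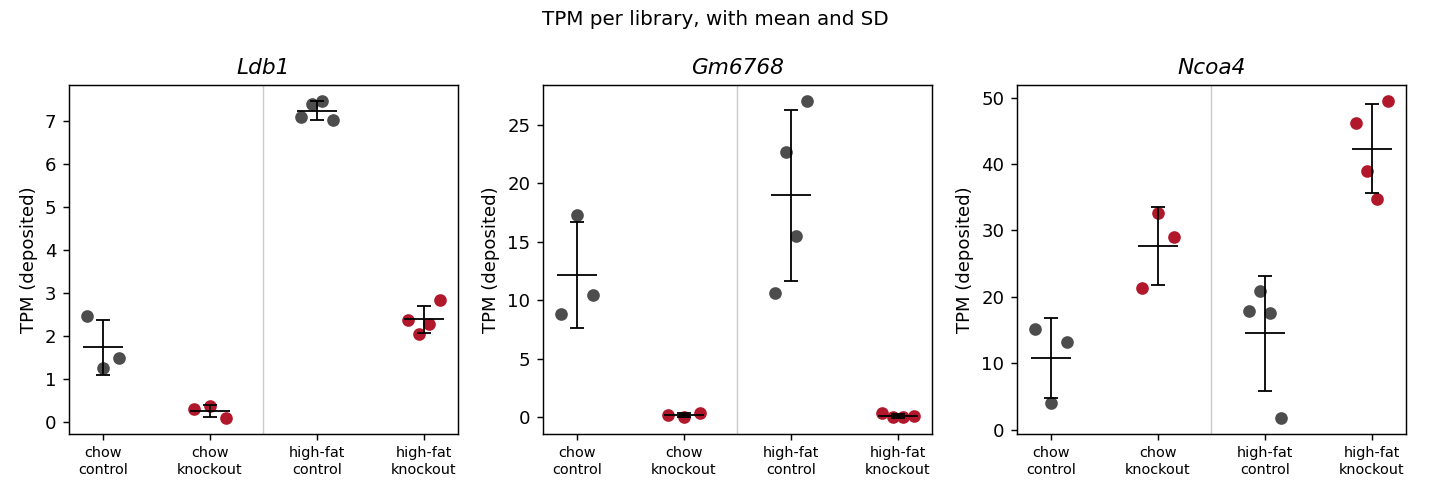
TPM of Ldb1, Gm6768 and Ncoa4 (vertical axes) in each mouse hepatocyte library by diet and genotype; points are libraries, horizontal lines are means and bars are SD, with 3 libraries per group on regular chow and 4 on the high-fat diet. Ldb1 and Gm6768 lay lower in every knockout library than in every control of the same diet, and Ncoa4 lay higher, though Ncoa4 did not pass the adjusted threshold (adjusted p = 0.263 on regular chow and 0.803 on the high-fat diet).

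In hepatocytes of mice on regular chow, Slco1a4, Adhfe1, Akr1d1 and Cyp3a25 were higher in the knockout, and Gm42427, Gm6768 and Gm23237 were among the genes that were lower. Slco1a4, a transporter that takes up organic anions and bile acids, rose from 1.84 ± 0.706 to 11.4 ± 5.39 TPM (SD, n = 3 and 3). Adhfe1, a mitochondrial hydroxyacid-oxoacid transhydrogenase, rose from 11.3 ± 2.09 to 29.6 ± 7.76 TPM. Akr1d1, the 5-beta-reductase of bile acid synthesis, rose from 15.6 ± 2.83 to 31.7 ± 6.48 TPM. Cyp3a25, a cytochrome P450 of drug and steroid metabolism, rose from 78.6 ± 17.4 to 162.6 ± 47.2 TPM, and is uncertain because reads can be shared within its gene family. The log2 fold changes were 1.95 for Slco1a4 (SE 0.18, limma adjusted p = 0.0238), 1.14 for Adhfe1 (SE 0.12, adjusted p = 0.0352), 0.81 for Akr1d1 (SE 0.08, adjusted p = 0.0238) and 0.85 for Cyp3a25 (SE 0.09, adjusted p = 0.0304). Among transcripts with no established function, Gm27501 rose from 2.52 ± 0.921 to 21.0 ± 8.09 TPM (adjusted p = 0.0116) and Epb41l4aos, antisense to Epb41l4a, rose from 3.92 ± 0.593 to 8.64 ± 1.68 TPM (adjusted p = 0.0297). Counting by strand is not given in the sources used here, so Epb41l4aos is uncertain. Gm42427 fell from 24.3 ± 6.21 to 6.19 ± 2.01 TPM (adjusted p = 0.0443). Gm6768, a pseudogene of Ncoa4 on chromosome 12 (119260933 to 119264275, mm10), fell from 12.2 ± 4.50 to 0.183 ± 0.177 TPM (log2 fold change -3.51, SE 0.35, adjusted p = 0.0297). Gm23237 was listed at 18.4, 16.5 and 12.2 TPM in the controls and at 0 in the 3 knockouts.

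Of 8930 genes tested on regular chow, 20 passed an adjusted p of 0.05, with 10 higher and 10 lower, and 5 of the 20 were protein-coding. Several of the 20, Gm23237 among them, were listed at 0 in a whole group, so their p-values rest mostly on the spread of the other group. At an unadjusted p under 0.05 there were 715 higher and 543 lower genes, and 55 genes passed an adjusted p of 0.1. Control and knockout values did not overlap for 762 genes (8.53%), where chance gives 10%. The count was 43 without control 1, 24 without control 2, 11 without control 3, 35 without knockout 1, 12 without knockout 2 and 13 without knockout 3, and it was 0 with only protein-coding genes tested. With TPM as deposited Akr1d1, Cyp3a25 and Epb41l4aos did not pass (adjusted p = 0.140, 0.120 and 0.117), and over all settings their highest adjusted p was 0.234 and their lowest 0.0142, 0.0305 and 0.00468. Slco1a4 passed in 8 of 16 other settings, Adhfe1 and Gm42427 in 6 of 16 each and Gm6768 in 6 of 15.

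Several hepatocyte metabolic gene groups lay higher in the regular chow knockout as groups. Of 23 tested lipogenesis genes 22 had a positive fold change (median log2 0.26, camera adjusted p = 5.68e-05; adjusted p = 0.147 with an estimated correlation). Fasn, the fatty acid synthase, was at 12.5 ± 2.78 and 26.7 ± 4.81 TPM in controls and knockouts (log2 0.88, adjusted p = 0.0973). Pklr, the liver pyruvate kinase, was at 35.3 ± 1.35 and 74.8 ± 14.5 TPM (adjusted p = 0.261), and Me1, the cytosolic malic enzyme, at 31.5 ± 3.75 and 63.0 ± 25.6 TPM (adjusted p = 0.277). No lipogenesis gene passed over all genes, 7 had an unadjusted p under 0.05, and 2 passed when adjusted over the list alone. Of 25 tested genes of the periportal zone 22 were positive (median log2 0.26, camera adjusted p = 0.000137; adjusted p = 0.147 with an estimated correlation), and 2 passed adjusted over the list alone against 0 over all genes, with 7 at an unadjusted p under 0.05. Among them Etnppl, a phosphoethanolamine lyase, was at 14.5 ± 5.56 and 44.0 ± 22.9 TPM (log2 1.33, adjusted p = 0.137), and Pigr, the polymeric immunoglobulin receptor, at 84.0 ± 24.1 and 135.9 ± 32.7 TPM (adjusted p = 0.154).

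Amino acid and urea cycle genes were positive in 25 of 30 (median log2 0.24, camera adjusted p = 0.000137; adjusted p = 0.592 with an estimated correlation). Gnmt, which methylates glycine, was at 215 ± 34.6 and 353 ± 79.6 TPM (adjusted p = 0.151), and Hpd of tyrosine breakdown at 769.9 ± 188 and 1207 ± 326 TPM (adjusted p = 0.196). None of the 30 passed over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05. Of 21 genes of gluconeogenesis and glycogen 14 were positive (median log2 0.23, camera adjusted p = 0.00183; adjusted p = 0.592 with an estimated correlation). Here 0 genes passed over all genes, 8 had an unadjusted p under 0.05 and 2 passed adjusted over the list alone. Ugp2, which makes UDP-glucose, was at 81.4 ± 13.1 and 151 ± 19.9 TPM (adjusted p = 0.0685), and Slc2a2, the main hepatic glucose transporter, at 33.9 ± 9.11 and 69.7 ± 6.25 TPM (adjusted p = 0.154). Bile acid genes were positive in 16 of 24 (median log2 0.19, camera adjusted p = 0.00300; adjusted p = 0.592 with an estimated correlation), with 1 gene, Akr1d1, past the threshold over all genes and 3 adjusted over the list alone. Abcg5, a sterol exporter, was at 8.02 ± 2.16 and 16.9 ± 3.36 TPM (adjusted p = 0.0990), and Slc10a1, the basolateral bile acid importer, at 107.8 and 171 TPM (SD 19 and 30.1, adjusted p = 0.151). Fatty acid oxidation genes were positive in 17 of 27 (median log2 0.08, camera adjusted p = 0.0304; adjusted p = 0.729 with an estimated correlation). Cyp4a10, a fatty acid hydroxylase, was at 8.28 ± 2.81 and 53.1 ± 40.7 TPM (adjusted p = 0.263). In this list 0 genes passed over all genes, 1 passed adjusted over the list alone and 8 had an unadjusted p under 0.05. Its call ended without controls 2 and 3 (camera adjusted p = 0.0834 and 0.262) or knockouts 2 and 3 (0.0523 and 0.262), each left out alone, and the gluconeogenesis and glycogen call ended without knockout 3 (0.109).

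Stress, acute-phase and male-biased genes lay lower in the regular chow knockout as groups. All 14 tested genes of the integrated stress and unfolded protein responses were negative (median log2 -0.62, camera adjusted p = 0.000137; adjusted p = 0.592 with an estimated correlation). Asns, the asparagine synthetase, was at 8.49 ± 3.24 and 1.77 ± 1.33 TPM (log2 -1.91, adjusted p = 0.173), and Xbp1, a transcription factor of the unfolded protein response, at 27.5 ± 3.63 and 22.4 ± 1.61 TPM (adjusted p = 0.401). In this list 0 genes passed over all genes, 1 passed adjusted over the list alone and 1 had an unadjusted p under 0.05. Male-biased genes were negative in 17 of 18 (median log2 -0.39, camera adjusted p = 0.000333; adjusted p = 0.592 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase, was at 142 ± 19.7 and 58.6 ± 19.8 TPM (adjusted p = 0.267), and Elovl3, a fatty acid elongase, at 154.6 ± 51.5 and 57.0 ± 38.5 TPM (adjusted p = 0.297). None passed over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05. Acute-phase genes were negative in 14 of 15 (median log2 -0.74, camera adjusted p = 0.00157; adjusted p = 0.592 with an estimated correlation). Saa1, a serum amyloid secreted in inflammation, was at 64.1, 626.9 and 1077 TPM in the controls and at 75.4, 21.4 and 40.8 TPM in the knockouts (adjusted p = 0.345), so 2 control mice set the difference. Of immediate early genes 11 of 12 were negative (median log2 -0.42, camera adjusted p = 0.0412; adjusted p = 0.592 with an estimated correlation), with Hsph1, a heat shock chaperone, at 36.2 ± 8.74 and 18.7 ± 10.9 TPM (adjusted p = 0.364). Both the acute-phase and the immediate early list held 0 genes past the threshold over all genes and 0 adjusted over the list alone, with 1 and 0 genes at an unadjusted p under 0.05. The immediate early call ended without controls 1 and 2 (camera adjusted p = 0.0834 and 0.0962) or knockouts 1 and 3 (0.268 and 0.0779), each left out alone. Of 34 lists tested, 10 passed and 0 of these held with an estimated correlation. Mup genes, which encode major urinary proteins, took 31.4% to 59.9% of all TPM in these libraries.

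On the high-fat diet few genes changed. Gm6768 fell from 18.96 ± 7.32 to 0.132 ± 0.179 TPM (SD, n = 4 and 4; log2 -4.13, SE 0.24, limma adjusted p = 0.000892). Gm42428, which the gene table used here does not list, fell from 170.1 ± 45.2 to 84.4 ± 10.7 TPM (log2 -1.08, SE 0.10, adjusted p = 0.00884). Cyp2a22, a cytochrome P450, rose from 0.0372 ± 0.0137 to 2.67 ± 1.03 TPM (log2 1.74, SE 0.19, adjusted p = 0.0278), and is uncertain because reads can be shared within its family. It passed in 7 of 16 other settings (highest limma adjusted p 0.159). Mir7653 was listed at 0 in the 4 controls and at 21.8, 19.5, 17.6 and 53 TPM in the knockouts. On regular chow Mir7653 lay the other way, at 3.41, 8.54 and 19.2 TPM in the controls and at 0, 0 and 8.84 TPM in the knockouts (adjusted p = 0.421), and the interaction had an adjusted p of 0.0790. Gm27671 was listed at 0 in the 4 controls and at 12.6, 24.7, 26.1 and 12.5 TPM in the knockouts. Of 11320 genes tested, 8 passed an adjusted p of 0.05, with 4 higher and 4 lower, and 2 of the 8, Ldb1 and Cyp2a22, were protein-coding. Several of the 8, Mir7653 and Gm27671 among them, were listed at 0 in a whole group, so their p-values rest mostly on the spread of the other group. At an unadjusted p under 0.05 there were 338 higher and 328 lower genes. The groups did not overlap for 189 genes (1.67%), where chance gives 2.86%. Leaving out 1 library gave 11 genes without control 1 or 3, 13 without control 2, control 4 or knockout 1, 16 without knockout 2 and 15 without knockout 3 or 4, numbers being column order only.

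Cholesterol synthesis genes lay higher in the high-fat diet knockout as a group. All 25 tested members were positive (median log2 0.49, camera adjusted p = 9.16e-08; adjusted p = 0.990 with an estimated correlation). Hmgcs1, which makes HMG-CoA at the head of the pathway, was at 24.8 ± 7.53 and 41.5 ± 15.7 TPM (adjusted p = 0.821), and Hsd17b7, a reductase of the late pathway, at 6.00 ± 1.93 and 9.94 ± 2.25 TPM (adjusted p = 0.660). Pmvk, the phosphomevalonate kinase, was at 10.3 ± 2.68 and 18.6 ± 7.36 TPM (adjusted p = 0.820), and Sc5d, a sterol desaturase, at 120 ± 26.7 and 182.6 ± 47.4 TPM (adjusted p = 0.800). Knockouts 1 and 4 lay above all controls in these genes, while knockouts 2 and 3 lay in or near the control range: Hmgcs1 was at 48.5 and 60.3 TPM in the former and 27.8 and 29.3 TPM in the latter, against 15.7 to 34 TPM in controls. Pmvk was at 25.8 and 23.9 TPM and at 11.4 and 13.1 TPM, against 7.94 to 12.9 TPM, and Sc5d at 209 and 235.9 TPM and at 145.7 and 139.7 TPM, against 91.4 to 144 TPM. The median log2 became 0.27 without knockout 4 (camera adjusted p = 0.00137) and 0.32 without control 4 (camera adjusted p = 0.00117). No member passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Amino acid and urea cycle genes were positive in 25 of 30 (median log2 0.14, camera adjusted p = 0.000391; adjusted p = 0.990 with an estimated correlation), with Cth, the cystathionine gamma-lyase, at 164.7 ± 41.1 and 268.9 ± 59.9 TPM (adjusted p = 0.710) and Ass1 of the urea cycle at 946.8 ± 182 and 1213 ± 140 TPM (adjusted p = 0.868). Lipogenesis genes were positive in 20 of 23 (median log2 0.28, camera adjusted p = 0.00487; adjusted p = 0.990 with an estimated correlation), with Acss2, an acetyl-CoA synthetase, at 24.0 ± 5.28 and 46.0 ± 19.2 TPM (adjusted p = 0.801) and Acsl3, which activates long-chain fatty acids, at 5.03 ± 1.44 and 9.37 ± 3.67 TPM (adjusted p = 0.791). These lists held 0 genes past the threshold over all genes and 0 adjusted over the list alone, with 1 and 2 genes at an unadjusted p under 0.05. The calls ended without control 4 for both (camera adjusted p = 0.109), and for lipogenesis also without knockout 1 (0.209) or knockout 3 (0.0559).

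Acute-phase genes were positive in 18 of 20 on the high-fat diet (median log2 0.17, camera adjusted p = 0.00926; adjusted p = 0.990 with an estimated correlation). Saa2, a serum amyloid, was at 45.3 ± 20.9 and 179 ± 183.7 TPM (adjusted p = 0.803), Orm2, an orosomucoid, at 11.6 ± 4.81 and 39.6 ± 38.1 TPM (adjusted p = 0.815) and Lcn2, a siderophore-binding lipocalin, at 9.50 ± 6.57 and 25.7 ± 23.4 TPM (adjusted p = 0.868). A single knockout library, knockout 2, stood apart in these genes, with 454 TPM of Saa2 (next 102.9), 96.7 TPM of Orm2 (next 23.6) and 60.7 TPM of Lcn2 (next 16.8). The acute-phase call ended without it (camera adjusted p = 0.145), without control 1 (0.350) and without control 4 (0.109). Kupffer cell markers were positive in 17 of 19 (median log2 0.13, camera adjusted p = 0.0336; adjusted p = 0.990 with an estimated correlation), with Lyz2, a lysozyme of macrophages, at 21.8 ± 5.35 and 34.6 ± 12.5 TPM (adjusted p = 0.879) and Tyrobp, a myeloid adaptor, at 15.4 ± 4.09 and 19.9 ± 2.68 TPM (adjusted p = 0.874). Clec4f and Cd5l of the same list hardly differed, at 31.4 ± 8.36 and 31.5 ± 3.14 TPM (log2 -0.06) and at 21.2 ± 5.48 and 23.5 ± 3.33 TPM (log2 0.08). Pericentral genes were positive in 15 of 22 (median log2 0.13, camera adjusted p = 0.0371; adjusted p = 0.990 with an estimated correlation), with Rhbg, an ammonia transporter, at 1.54 ± 0.398 and 2.84 ± 0.511 TPM (adjusted p = 0.460) and Glul, the glutamine synthetase of the innermost pericentral cells, at 425 ± 119.6 and 587 ± 54.8 TPM (adjusted p = 0.771). Endothelial markers were negative in 19 of 20 (median log2 -0.14, camera adjusted p = 0.00696; adjusted p = 0.990 with an estimated correlation), Robo4, an endothelial guidance receptor, having 2.53 ± 0.646 and 1.81 ± 0.599 TPM (adjusted p = 0.820) and Eng, a TGF-beta co-receptor, 9.57 ± 1.59 and 8.43 ± 2.00 TPM (adjusted p = 0.874). Interferon genes were negative in 12 of 16 (median log2 -0.14, camera adjusted p = 0.0299; adjusted p = 0.990 with an estimated correlation), Usp18, a deISGylating protease, having 3.68 ± 1.28 and 2.75 ± 0.657 TPM (adjusted p = 0.820) and Ifi27 179.9 ± 20.5 and 163 ± 19.9 TPM (adjusted p = 0.868). Fatty acid oxidation genes were negative in 24 of 28 (median log2 -0.08, camera adjusted p = 0.0371; adjusted p = 0.990 with an estimated correlation). Acadvl, the very-long-chain acyl-CoA dehydrogenase, was at 162 ± 21.9 and 152.6 ± 20.3 TPM (adjusted p = 0.803). In all 6 of these lists 0 genes passed over all genes. Adjusted over the list alone, 1 pericentral and 1 fatty acid oxidation gene passed and 0 of the other lists, and each of the 6 held between 0 and 3 genes at an unadjusted p under 0.05. The Kupffer call ended without controls 1 and 2 (camera adjusted p = 0.439 and 0.109) or knockouts 1, 3 and 4 (0.103, 0.627 and 0.0670), and the pericentral call without controls 1, 3 and 4 (0.0724, 0.0723 and 0.109) or knockouts 1 and 4 (0.0854 and 0.375), each left out alone. The endothelial call ended without control 4 (0.509) or knockout 2 (0.422), the interferon call without controls 2, 3 and 4 (0.118, 0.377 and 0.0539) or knockouts 1, 3 and 4 (0.135, 0.0638 and 0.0670), and the fatty acid oxidation call without controls 2 and 4 (0.157 and 0.638) or knockouts 2 and 3 (0.238 and 0.235). Of 38 lists tested, 9 passed and 0 held with an estimated correlation, and without control 4 only 2 lists passed.

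**Figure D2:**
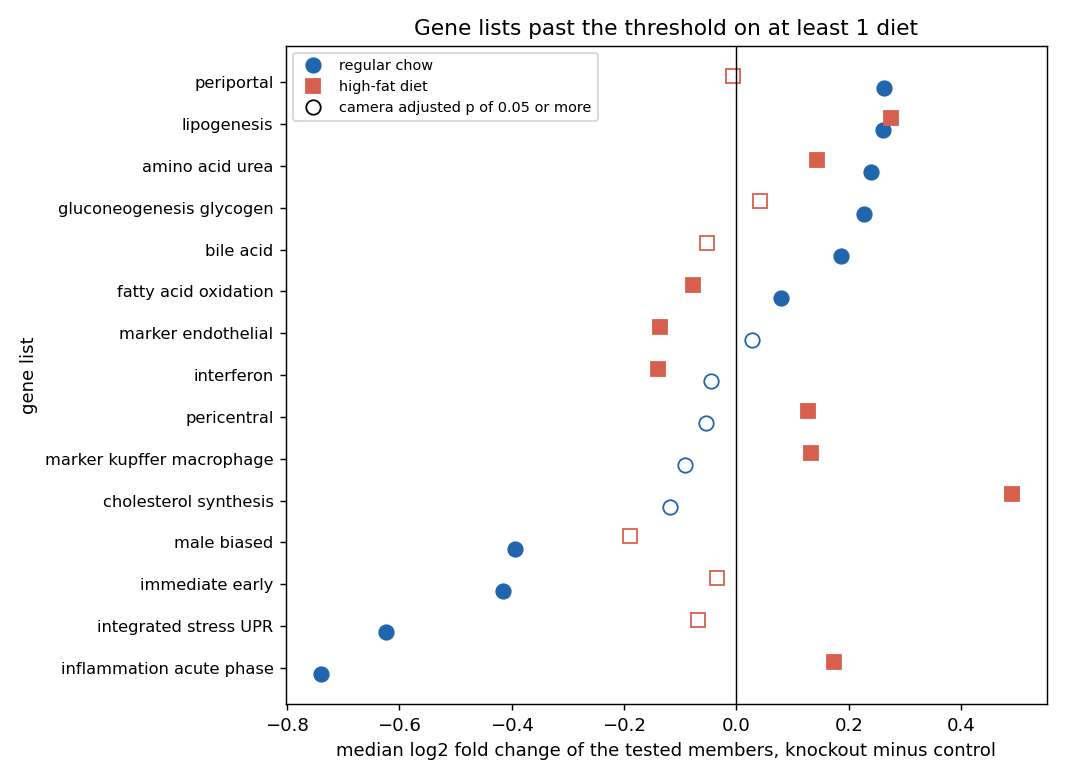
Median log2 fold change (knockout minus control, horizontal axis) of the tested members of each gene list that passed the camera threshold on at least 1 diet; circles are regular chow, squares the high-fat diet, and filled symbols passed. Cholesterol synthesis stood at 0.49 on the high-fat diet, and the acute-phase list at -0.74 on regular chow; 0 of the lists passed with an estimated correlation.

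Transcription factors of hepatocyte identity and the known partners of LDB1 gave no detectable difference on either diet. Hnf4a, a nuclear receptor central to hepatocyte identity, was at 41.8 ± 6.96 and 40.0 ± 8.70 TPM on regular chow (adjusted p = 0.639) and at 44.6 ± 7.19 and 49.9 ± 7.08 TPM on the high-fat diet (adjusted p = 0.930). Cebpa, another factor of hepatocyte identity, was at 13.2 ± 4.59 and 21.5 ± 2.18 TPM on regular chow (adjusted p = 0.321) and at 61.1 ± 8.95 and 59.3 ± 5.98 TPM on the high-fat diet (adjusted p = 0.907). The log2 fold changes of the pioneer factor Foxa2 were -0.01 on regular chow (adjusted p = 0.991) and 0.37 on the high-fat diet (adjusted p = 0.872). Foxa1, a related pioneer factor, was tested on the high-fat diet alone (log2 0.06, adjusted p = 0.917). Lmo4, a LIM-only partner of LDB1, had log2 fold changes of -0.32 (adjusted p = 0.481) and 0.13 (adjusted p = 0.874), and Ssbp3, a single-stranded DNA-binding protein that stabilises LDB1, 0.15 (adjusted p = 0.761) and -0.05 (adjusted p = 0.956). Ldb2, the paralog of Ldb1, stayed below the TPM filter.

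The diets were compared by the difference between their knockout effects, and 3 transcripts passed. Gm23550 was listed at 10.3, 13.2 and 5.55 TPM in the regular chow knockouts and at 0 in the other 3 groups. Gm38298 was listed at 8.91, 2.86 and 7.89 TPM in the regular chow controls and at 0 elsewhere. Gm24824 was listed at 3.14, 4.95, 8.37 and 3.23 TPM in the high-fat diet controls and at 0 elsewhere. Their limma adjusted p were 3.18e-05, 0.000442 and 0.0111, out of 11975 genes tested, and 23 genes passed an adjusted p of 0.1. Groups listed at 0 show no spread, so the p-values of these transcripts rest mostly on the libraries of a single group. They do not fully measure the spread between mice. Inmt, an indolethylamine methyltransferase, came close: it was at 27.7 ± 11.1 and 159 ± 83.9 TPM on regular chow and at 336.5 ± 55.9 and 398.9 ± 24.0 TPM on the high-fat diet (interaction log2 -2.10, adjusted p = 0.0550). Serpina3m, an acute-phase protease inhibitor of a multigene family and so uncertain, was at 256 ± 29.4 and 164 ± 55.6 TPM on regular chow and at 147.6 ± 8.22 and 176 ± 19.7 TPM on the high-fat diet (interaction log2 1.01, adjusted p = 0.0550). Every library left out raised the count over 1.5 times, to 121 without regular chow control 1, 9 without regular chow control 2, 11 without regular chow control 3, 8, 5 and 8 without regular chow knockouts 1, 2 and 3, 6, 7, 5 and 8 without high-fat diet controls 1 to 4, and 10, 5, 6 and 8 without high-fat diet knockouts 1 to 4. Diet, age and the deposited table change together between the 2 sets of mice, and the tables were normalised separately.

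As groups, 8 of 38 lists differed between the diets in their knockout effect. Cholesterol synthesis (median log2 0.59, camera adjusted p = 8.31e-05; adjusted p = 0.766 with an estimated correlation), acute-phase (1.01, camera adjusted p = 0.000220; adjusted p = 0.689 with an estimated correlation) and stress response genes (0.56, camera adjusted p = 0.00118; adjusted p = 0.557 with an estimated correlation) had the higher knockout effect on the high-fat diet. Fatty acid oxidation (-0.16, camera adjusted p = 0.00280; adjusted p = 0.766 with an estimated correlation), mitochondrially encoded (-0.20, camera adjusted p = 0.00286; adjusted p = 0.627 with an estimated correlation) and bile acid genes (-0.20, camera adjusted p = 0.00470; adjusted p = 0.557 with an estimated correlation) had the lower effect there. So did periportal (-0.18, camera adjusted p = 0.00470; adjusted p = 0.627 with an estimated correlation) and gluconeogenesis and glycogen genes (-0.17, camera adjusted p = 0.0159; adjusted p = 0.627 with an estimated correlation). None of their genes passed over all genes, and adjusted over the list alone 2 bile acid, 2 periportal, 2 gluconeogenesis and glycogen and 1 fatty acid oxidation genes passed, with 8, 6, 6 and 6 genes at an unadjusted p under 0.05 and a lower effect. In the other lists, 3 cholesterol synthesis, 8 acute-phase, 2 stress response and 4 mitochondrially encoded genes had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. The acute-phase difference leaned on few libraries. Saa1 was at 64.1, 626.9 and 1077 TPM in the regular chow controls and at 984 TPM in high-fat diet knockout 2 (next 140). Hmgcs1, Pmvk and Sc5d lay clearly above the controls in high-fat diet knockouts 1 and 4 alone. The interaction lists were not refitted with a library left out or set against other splits.

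Gm6768 was the single gene that passed an adjusted p of 0.05 in the same direction on both diets, out of 8770 tested in both, and Ldb1 missed it on regular chow (adjusted p = 0.0520). The overlap became 2 genes with TPM as deposited and 0 at a pseudocount of 5. Regular chow called 6 of these lower and the high-fat diet 3, and 1 shared gene compares with 0.00205 by chance (Fisher's exact test, two-sided, p = 0.00205). That gene, Gm6768, is a pseudogene of Ncoa4, which lay higher in every knockout, so its fall may be one of read assignment between the copies. Of higher genes, limma called 7 and 2 and 0 were shared. At an unadjusted p under 0.05, 49 higher genes were shared where 21.4 are given by independence (Fisher's exact test, two-sided, p = 2.71e-08), and 29 lower genes where 14.4 are (p = 0.000271). Among the lower genes was Ldb1. Fold changes correlated weakly across genes, which are not independent replicates (Pearson r = 0.13, Spearman rho = 0.01).

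In HepG2 cells the authors' deposited table called more genes lower than higher after LDB1 loss. Of 58350 genes in the authors' deposited table, 17426 had an adjusted p, and 397 passed 0.05, with 117 higher and 280 lower (70.5% lower). In the authors' deposited table an absolute log2 fold change of at least 1 was given for 96 of the higher and 227 of the lower genes, with medians of 1.34 among the higher and -1.30 among the lower genes. Among the genes with the largest changes in the authors' deposited table, ENSG00000113140 had a log2 fold change of 4.58 (adjusted p = 5.44e-77) and ENSG00000198053 of 4.17. The authors' deposited table gave ENSG00000092421 a log2 fold change of -5.06 (adjusted p = 5.53e-49) and ENSG00000117114 of -4.64. The files do not pair these identifiers with gene names, and the authors' deposited table holds no values per sample.

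LDB1 occupied a common set of sites in the control HepG2 samples. The 2 replicates had 4024 and 5622 LDB1 peaks, of which 3366 (83.6%) and 3340 (59.4%) overlapped the other replicate, against 0.348% and 0.249% after peaks were shifted by 50 kb. Of the 1006 and 1406 peaks with the highest fold enrichment in each replicate, 99.7% and 97.6% overlapped. Ranked by the lower of their 2 fold enrichments, the 3331 shared regions were led by chromosome 9:6590630 to 6591190 (hg38) with fold enrichments of 63.3 and 64.1. Next came 1:86774403 to 86775040 (59.4 and 60.9), 16:67363194 to 67363816 (56.8 and 60.9), 2:18800423 to 18801057 (56.2 and 75) and 3:11618880 to 11619384 (52.3 and 49.3). The last 3 of these overlapped no H3K27ac region. Of the shared LDB1 regions 1618 (48.6%, 95% Wilson interval 46.9% to 50.3%, counting error only) overlapped H3K27ac of both controls, against 3.11% after the shift, and 8.04% of the 20411 H3K27ac regions held LDB1. No annotation of hg38 was used here, so these regions were not assigned to genes.

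LDB1 loss was accompanied by changes in H3K27ac in a small part of the marked regions of HepG2 cells. Of 38016 merged regions, 1133 (2.98%) had a peak in both controls and in neither knockout (lost), 1639 (4.31%) in both knockouts and in neither control (gained), and 17016 (44.8%) in all 4 libraries (kept). Lost and gained regions were short and weak, with median widths of 463 and 461 bp against 1378 bp for kept regions and median highest fold enrichments of 5.48 and 5.41 against 8.86. The lost and gained sum of 2772 compares with 1022 and 1341 for the other splits of the 4 libraries, and with 3 splits no test can pass. Left-out libraries raised the lost count to 2856 without control 1, 5406 without control 2 and 2115 without knockout 2, and the gained count to 3195 without control 1, 6448 without knockout 1 and 4411 without knockout 2, since fewer libraries then have to hold the peak or lack it.

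LDB1 sites lay less often at lost than at kept H3K27ac regions of HepG2 cells, and for gained regions the difference held in 1 of 4 classes of region width. A shared LDB1 region overlapped 29 of the lost (2.56%), 70 of the gained (4.27%) and 1644 of the kept regions (9.66%; Fisher's exact test, two-sided, p = 4.89e-20 for lost and 4.04e-15 for gained against kept). Regions are not independent replicates, and the HepG2 samples may be technical, so these p-values do not measure the spread between cultures. Kept regions were also stronger (median highest fold enrichment 8.86 against 5.48 for lost and 5.41 for gained), and strength was not matched. The odds ratios of 0.25 and 0.42 became 0.42 and 0.71 within 4 classes of similar region width. From the narrowest to the widest class, the odds ratios of lost regions were 0.19, 0.35, 0.49 and 0.75 (Fisher's exact test, p = 0.296, 4.19e-05, 0.0218 and 0.791). Those of gained regions were 0.88, 0.48, 0.94 and 1.00 (Fisher's exact test, p = 1, 0.000549, 0.841 and 1). With equal list lengths the odds ratios within width classes were 0.40 for lost and 0.90 for gained regions. Lost regions held LDB1 less often than gained ones (Fisher's exact test, p = 0.0167), which did not hold with the LDB1 peaks of replicate 1 (p = 0.267) or replicate 2 alone (p = 0.0875). With equal list lengths the shares were 2.43% and 5.45% (odds ratio 0.43, Fisher's exact test, p = 0.000133).

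**Figure D3:**
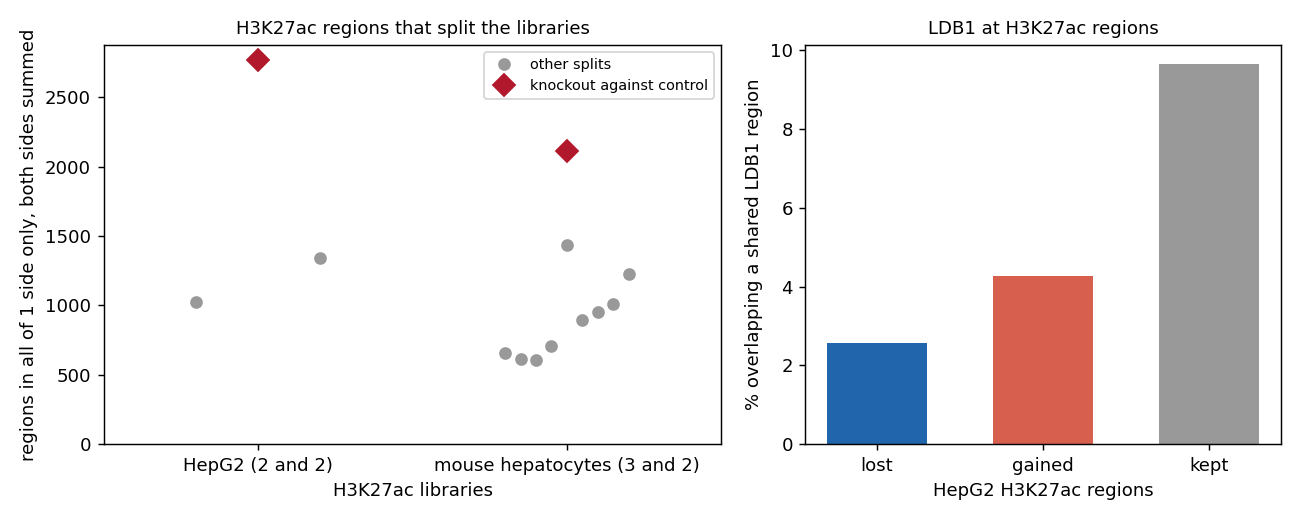
Left, number of H3K27ac regions with a peak in all libraries of 1 side and in 0 of the other (vertical axis, both sides summed) for each split of the HepG2 and the mouse libraries; diamonds are knockout against control and circles the other splits. Right, percent of lost, gained and kept HepG2 H3K27ac regions that overlap a shared LDB1 region. The real split gave 2772 regions in HepG2 and 2112 in the mouse, and LDB1 lay at 2.56%, 4.27% and 9.66% of lost, gained and kept regions.

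Lost and gained H3K27ac regions made up a small part of the marked regions of mouse hepatocytes. Of 52881 merged regions, 1435 were lost, 677 gained and 22596 kept, with median widths of 469, 413 and 1489 bp. A gene body held 70.9% of lost, 88.8% of gained and 84.5% of kept regions. The sum of 2112 compares with 610 to 1435 for the other 9 of 10 splits, too few for a share under 0.05. Lost regions need a peak in 3 libraries and gained ones in 2, so the counts do not rank the directions. Their order turned without knockout 3, the mouse library with the fewest tags (9905051) and peaks (37324), to 2230 lost and 4755 gained. The counts without 1 library were 2617, 2289 and 2590 lost without controls 1, 2 and 3, 3340 lost without knockout 1, and 1091 and 2846 gained without control 1 and knockout 1.

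At the Ldb1 gene itself (chromosome 19:46031525 to 46048145, mm10) the mouse knockouts lacked 1 region within the gene, 46039048 to 46039930 (lowest fold enrichment of the control libraries 6.55), and had 6 gained regions within 50 kb, such as 46031698 to 46033643 and 46041466 to 46043068 (lowest fold enrichments of the knockout libraries 6.17 and 5.37). These were singled out after their values were seen. Cre removes a floxed segment of this gene, whose position was not used here, so absent DNA and lost acetylation cannot be told apart. A gained region (46040025 to 46040518) lay directly beside the lost one, so the 2 need not be separate changes. Near the genes that changed on regular chow, a lost region (18:33779671 to 33780205) lay 14687 bp from Epb41l4aos, another (19:5433280 to 5433900) lay 17464 bp from the pseudogene Gm6293, named after its values were seen, and 1 gained region (6:37605010 to 37605190) lay 30089 bp from Akr1d1. Of the 20 changed genes 10 could be placed. A lost region lay within 50 kb of 2 of 7 that rose (28.6%) and 0 of 3 that fell, against 18.9% of other genes (Fisher's exact test, two-sided, p = 0.623 and 1, adjusted p = 1 for both). A gained region lay near 1 of 7 (14.3%) and 0 of 3, against 10.8% (Fisher's exact test, p = 0.551 and 1, adjusted p = 1 for both).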

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

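The tests of single libraries and of the interaction were planned, and the gene names tested for single libraries were chosen after the values were seen. A library stood apart from the other 3 of its group in 15 of 93 high-fat diet groups tested by Dixon's criterion for 4 values, where chance sets a library apart in about 5% of independent groups. These groups share libraries and their genes were chosen after the values were seen, so an excess over chance is not shown. The same knockout library gave the highest values of acute-phase genes: 984 TPM of Saa1 (next 140), 454 TPM of Saa2 (next 102.9), 96.7 TPM of Orm2 (next 23.6) and 60.7 TPM of Lcn2 (next 16.8). A single control library gave the highest control values of the same genes, with 121 TPM of Saa1 (next 66.3), 76.3 of Saa2 (next 38.3), 18.7 of Orm2 (next 9.76) and 19.3 of Lcn2 (next 7.12). That control also held the highest Lmo4, with 5.33 TPM (next 3.77). Low values stood apart for Ass1 in a knockout (1006 TPM, next 1249), Lyz2 in a knockout (16.0, next 38.9) and Cebpa in a control (47.7, next 64.3). High values stood apart for Hbb-bs (1793 TPM, next 771), Mir7653 (53, next 21.8) and the share of TPM taken by Mup genes (23.1%, next 12.3%), each in a knockout.

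The knockout effect differed between the diets for Gm23550 (interaction log2 -3.78), Gm38298 (3.36) and Gm24824 (-2.18). Each is listed at 0 in all libraries of 3 groups, so these fitted values depend on the pseudocount and are not fold changes. Chance was not excluded for this count: 53 of 100 drawn splits of the libraries within the diets gave at least the 3 genes of the real split, and the highest other split gave 52. A split with several times the real count may reflect a structure of the samples, which was not tested. The highest split kept the regular chow genotypes apart and mixed only the high-fat diet libraries, so it still held the regular chow contrast.

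Lists whose knockout effect differed between the diets were cholesterol synthesis (median interaction log2 0.59), acute-phase genes (1.01), stress response genes (0.56), fatty acid oxidation (-0.16), mitochondrially encoded genes (-0.20), bile acid genes (-0.20), periportal genes (-0.18) and gluconeogenesis and glycogen (-0.17). With an estimated correlation 0 of these lists passed. They were not refitted with a library left out or set against other splits. Diet, age and the deposited table change together, so they cannot be told apart as sources of any of these differences.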

How the results depend on the processing

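Other pseudocounts, tests on protein-coding genes alone, the estimated correlation for the interaction lists, the alternatives to the overlap other than the block, and genes at an unadjusted p near H3K27ac regions were tests chosen after the data were seen. The cause of a change was not tested unless named. Of named genes, 175 values under other settings kept direction and side of the threshold, 67 kept direction but not the threshold, 3 newly passed and 0 reversed, and with a library left out 120 kept both and 70 kept direction alone. Ldb1 on the high-fat diet passed in 16 of 16 settings (highest adjusted p 0.0115), and on regular chow in 3 of 15 (adjusted p 0.000337 to 0.231, log2 -2.57 to -0.37). Gm6768 passed in 16 of 16 and 6 of 15. Cyp2a22 passed in 7 of 16, Slco1a4 in 8 of 16, Adhfe1, Akr1d1, Cyp3a25 and Gm42427 in 6 of 16 each, Epb41l4aos in 5 of 15, Gm27501 in 10 of 15 and Gm23237 in 14 of 15. Depth is unknown for TPM, and no setting could correct for it.

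Regular chow gave 20 genes, and 54 with TPM as deposited (29 higher, 25 lower, the median of all genes then moving to 0.13, so changes there are relative to it), 7 with no filter, 2 at a mean TPM of at least 5, 0 with protein-coding genes alone (limma, 1110 at an unadjusted p under 0.05), 233 with a spread shared by all 14 mouse libraries (147 higher, 86 lower, 16 of the 20 among them) and 11 to 43 with a library left out. The high-fat diet gave 8 genes, and 16 with no filter, 4 at a mean TPM of at least 5, 2 with protein-coding genes alone and 11 to 16 with a library left out. The interaction gave 3 genes, and 5 with TPM as deposited, 13 with no filter, 11 at a pseudocount of 0.1, 6 at 0.5, 0 with protein-coding genes alone (limma, 1286 at an unadjusted p under 0.05) and 5 to 121 with a library left out, 121 without regular chow control 1. The overlap of 1 gene became 2 with TPM as deposited, 0 with protein-coding genes alone and 0 at a pseudocount of 5. With an estimated correlation, 10 regular chow, 9 high-fat diet and 8 interaction lists became 0, and leaving out a library gave 8 to 13 regular chow and 2 to 10 high-fat diet lists, 2 without control 4. Median-of-ratios scaling gave 23, 8 and 4 genes.

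The replicate numbers of regular chow mice gave no sign of pairing: same-number deviations correlated at -0.14, -0.13 and 0.06 across genes, and those of other pairs at -0.12 to 0.22. Deviations were taken from the mean of only 3 mice per group, so this check cannot exclude a pairing. With the number as a block, 0 genes passed on regular chow (limma, 1043 at an unadjusted p under 0.05) and the overlap held 0 genes, with fewer residual degrees of freedom. No paired analysis was possible because the columns of the high-fat diet carry no replicate numbers, for that diet and the interaction, and because the deposited table holds no samples, for HepG2 RNA.

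Of shared LDB1 regions 48.6% overlapped H3K27ac, and 34.3% with at least 50% of the region covered, 42.4% at a −log10 q of at least 5, and 45.5% and 44.0% for replicates 1 and 2 alone. At a −log10 q of at least 5, HepG2 lost regions fell from 1133 to 611 and mouse gained regions from 677 to 300. With a library left out, HepG2 had 1670 to 5406 lost and 2247 to 6448 gained regions, and the mouse 2230 to 3340 lost and 877 to 4755 gained, because fewer libraries must then hold or lack the peak. Near lost regions lay 0% of genes that rose within 10 kb and 33.3% of those that fell within 100 kb. Near gained regions lay 0% of genes that rose within 10 kb and 14.3% within 100 kb, and 33.3% of genes that fell with equal list lengths. These directions against other genes turned on 7 and 3 genes. At an unadjusted p, 31.0% of genes that rose lay within 100 kb of lost regions (Fisher's exact test, p = 0.0598, past the threshold within 50 kb) and 9.41% of those that fell within 10 kb, opposite to 50 kb. With equal list lengths, 11.8% of genes that rose lay near gained regions, opposite to all peaks, and 15.9% of those that fell (Fisher's exact test, p = 0.00223, newly past the threshold).

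Not run were count tests for the mouse tables, refits of HepG2 RNA, the HepG2 overlap with the mouse, motifs at LDB1 peaks, and LDB1 or H3K27ac near HepG2 genes.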

Other observations

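The tests of Gm6768 against Ncoa4 and of blood and other markers between the diets were chosen after the result was seen, as were those of genes at an unadjusted p near H3K27ac regions; the tests of splits, of male-biased genes and of the DNA around Gm6768 were written before their own values were seen.

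Samples of the high-fat diet held more RNA of several markers of cells other than hepatocytes than samples of regular chow, in tables normalised separately. Genes with a mean of at least 1 TPM lay higher there, by a median of 0.78 on log2(TPM + 1). Erythroid, Kupffer, stellate and cholangiocyte lists lay above this, with medians of 5.44, 1.78, 1.51 and 1.09 over 6, 22, 18 and 5 genes. The lymphocyte list (0.89, 11 genes) lay close to it and the endothelial list (0.64, 23 genes) below it. List genes needed 1 TPM in any library, so some entered through the diet where they are high, and these medians are not matched to 0.78. Among genes with a regular chow mean of at least 1 TPM, median log2 ratios were 6.36 for erythroid, 2.31 for Kupffer, 3.07 for stellate and 1.35 for endothelial genes. All such genes had 0.88. The genes given next are the highest of their lists. Hbb-bs, a beta-globin of red cells, ran from 1.45 to 24.1 TPM on regular chow and from 585.5 to 2234 TPM on the high-fat diet. Stab1, a scavenger receptor of sinusoidal endothelium, ran from 4.44 to 28.3 and from 108 to 166 TPM. Clec4f, a lectin of Kupffer cells, ran from 3.55 to 8.72 and from 21.4 to 41.8 TPM, and Ecm1, of stellate cells, from 2.83 to 11.5 and from 46.9 to 90.8 TPM. Of the marker lists, 10 of 23 endothelial, 5 of 9 erythroid, 14 of 24 Kupffer and 6 of 23 stellate genes were tested on regular chow, and 0, 0, 0 and 5 members stand in another list. The cholangiocyte and lymphocyte lists held fewer than 5 genes tested on regular chow. The labels call these samples hepatocytes and describe no step that would remove such cells.

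Genes that leaned higher in the regular chow knockout lay near lost H3K27ac regions more often than other genes. Of 646 genes higher at an unadjusted p under 0.05, 150 (23.2%) had a lost region within 50 kb, against 18.4% of other genes (Fisher's exact test, two-sided, p = 0.00316, adjusted over 4 tests 0.0126) and 18.9% of matched draws (p over the draws = 0.00340, adjusted 0.0136). Within 10 kb the shares were 14.6% and 9.48% (Fisher's exact test, p = 8.21e-05), and within 100 kb, where the call ended, 31.0% and 27.5% (p = 0.0598, adjusted 0.203). Of genes that leaned lower, 20.9% lay near a lost region (Fisher's exact test, p = 0.162) and 13.6% near a gained one (p = 0.0573), which passed with equal list lengths (15.9%, p = 0.00223, adjusted 0.00892). Genes are not independent replicates in these tests.

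The counts of genes and lists were set against other splits of the same libraries. Regular chow has 10 splits, too few for a share under 0.05: the real split gave 20 genes and the highest other 10, and 10 lists against 15 (4 splits gave as many). On the high-fat diet chance was not excluded, as 2 of 35 splits gave at least the 8 genes of the real split (highest other 9) and 19 of 35 at least its 9 lists (highest other 18).

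Male-biased genes lay lower as a list in the regular chow knockout (camera adjusted p = 0.000333; adjusted p = 0.592 with an estimated correlation). Females among the knockouts are argued against, since Xist reached at most 0.00376 TPM and the 4 summed Y genes at least 27.1 TPM in these mice. Mup genes taking much of the TPM did not carry the call, which kept an adjusted p of 0.00677 (median log2 -0.34) once they were left out and the rest rescaled. An acute-phase response in part of the controls stays open: the higher of the adjusted p without control 2 or 3 was 0.00224, but the bound set beforehand was wrong, since either fit keeps the other control with high Saa1 (1077 or 626.9 TPM). Genotype stays open as a hypothesis, as does chance.

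Gm6768 fell on both diets, and Ncoa4, of which it is a copy, lay higher in every knockout. Their summed TPM went from 23.0 ± 1.49 to 27.9 ± 5.74 on regular chow and from 33.5 ± 7.03 to 42.4 ± 6.86 on the high-fat diet (log2 ratios 0.28 and 0.34), so a candidate explanation is that reads of 1 transcript were assigned to the copy in controls and to Ncoa4 in knockouts. A difference in the DNA around Gm6768 cannot be told apart from this, because only 3 genes within 5 Mb were tested (0 changed on both diets). A strain or allele difference that moves reads between the copies may underlie it and was not tested.

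The higher non-hepatocyte RNA on the high-fat diet was weighed against a lower share of hepatocyte RNA. The bound first set, a list with its quartiles below 0, was replaced after all 6 medians were seen above 0 on the pseudocount scale, where quartiles stood apart (1.91 to 6.09 for erythroid, 0.63 to 1.17 for lymphocyte genes). Log2 ratios of mean TPM were tried afterwards under 2 filters on low TPM. Endothelial genes then had a median of 1.35 and stellate genes of 3.07, against 0.88 for all genes. The gap of 1.08 between their quartiles was the largest of any pair of lists. Cell types need not rise by the same factor when the hepatocyte share falls, so the gap cannot decide. A lower hepatocyte share stays open. Another library type stays open. Histone genes with 1 TPM or more in any library differed by a median of 0.77, and genes with a mean of at least 1 TPM by 0.78. Malat1 and Neat1 differed more. Malat1 ran from 1.19 to 4.44 TPM on regular chow and from 19.7 to 46.8 TPM on the high-fat diet, and Neat1 from 0.619 to 2.22 and from 36.1 to 84.4 TPM. Diet and age also remain open, as untested.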
